A study of Mus musculus with 6 samples.

How the data were processed

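RNA was measured by sequencing in ID4-GFP+ spermatogonia, the mitotic germ cells of the testis that carry a green fluorescent reporter for the transcription regulator ID4. The labels give 6 mouse samples in 2 groups, 3 controls and 3 with ID4 overexpression in germ cells. Per the labels' protocols, RNA was extracted with Trizol and cDNA was primed with oligo d(T), which favours polyadenylated transcripts. TopHat, Cufflinks and the mm9 build are named without versions in the submitters' processing notes. The Bright and Dim reporter fractions that the series title mentions are not analysed here.

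The deposited table gives FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) per gene, as 1 value per group that the authors had already combined over the replicates. The same deposited table gives a p-value and a q-value per gene from the authors' own test, with a test status, and per the file headers its layout is that of a gene-level Cuffdiff comparison. How the libraries were scaled and whether strand was used in counting are not stated. No per-sample values, counts or standard errors were used here, so the depth of each library is unknown, and no replicate SD or counting interval is given. The table has 23355 gene entries and 1 emptied line. The authors tested 10990 entries (status OK), did not test 12209, and marked 156 as having too little data. The q-values were checked against a Benjamini-Hochberg adjustment of the authors' p-values over the tested entries, and differed from it by at most 4.77e-05. The smallest p-value in the table, 5e-05, is shared by 657 called genes, so p-values do not rank those genes.

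Although the processing notes name mm9, the positions in the table match GRCm38 (mm10). Of 21624 symbols found in GENCODE M21, 21426 (99.1%) overlapped the GRCm38 gene of the same name, and 36 entries lie on scaffolds named as in that build. Deposited start positions count from 0, and adding 1 matched 6605 annotated gene starts, against 702 without it. Coordinates are therefore printed 1-based and as GRCm38.

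Fold changes were recomputed as overexpression FPKM over control FPKM, because 661 cells of the deposited log2 column hold spreadsheet error text. Elsewhere the recomputed log2 values differed from the authors' by at most 3.04e-05. A gene was called higher or lower at an authors' q of 0.05 or less with status OK. No model was refitted, and no pseudocount was used apart from the alternatives. Of the tested genes, 5 were listed at 0 in a group; none of them was called, and they have no fold. A further 27 entries have symbols that a spreadsheet turned into dates, 4 of them called, and 100 entries hold several symbols; they stay in the counts and are not named.

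These choices were made before the data were examined: the threshold, the gene lists, the tests, the rule for named genes and the other settings tried, apart from those added later. The rule names Id4 first. It then takes the 10 largest and the 10 smallest log2 fold changes among called genes with FPKM of at least 1 in the higher group and above 0 in both. From each list it takes up to 4 called members with the largest absolute change, or the 2 most abundant tested members where none was called. Not every gene that the rule takes is described here. Of 28 lists, those with enough tested members were compared with the other tested genes by Fisher's exact test, two-sided, per direction, with Benjamini-Hochberg adjustment over 50 tests. Each list's median log2 fold change was ranked among 10000 random lists of the same size, matched on 10 classes of mean expression. That percentile describes genes in these libraries, and genes are not independent replicates. Calls per chromosome were compared by Fisher's exact test, two-sided, adjusted over 42 tests. Medians per chromosome and per 10 Mb interval used tested genes with FPKM of at least 5 in either group and intervals with at least 10 such genes. Bootstrap intervals (95%) used 10000 resamples of genes.

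Alternatives were q thresholds of 0.01 and 0.1, a minimum FPKM of 1, a minimum absolute log2 fold change of 1, pseudocounts of 1 and 0.1, subtraction of the median log2 fold change, single named genes, and another background for the Fisher tests. Leaving out chromosome 15 and leaving out Id4 were added after seeing the data. Alternatives that need values per sample (leaving out replicates, another tool, other splits of the samples) were not run.

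The list and set tests were tested on simulated data for this comparison, in 100 simulations over 10572 genes. Of lists of 20 genes with no shift, 4% fell outside the central 95% of random lists, and 100% of lists shifted by 0.7 on the log2 scale were recovered. Fisher's exact test fell under 0.05 in 1% of unplanted sets of 400 genes and in 100% of sets with 60 planted lower calls. Genes outside chromosome 15 were shuffled within classes of mean expression and sets were drawn at random. The simulations therefore do not cover genes that vary together, as members of real lists may. Fisher's exact test was not simulated at the smaller sizes of the gene lists. The ranking of medians was not simulated for shifts below 0.7 or for lists of other sizes, so its power there is unknown. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with GENCODE M21 for gene positions.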

Results

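The transcriptomes of ID4-GFP+ spermatogonia were compared between mice that overexpress ID4 constitutively in the germ line (3 samples) and control mice (3 samples). ID4 is an inhibitor of DNA binding, a protein that sequesters basic helix-loop-helix (bHLH) transcription factors, and its reporter marks spermatogonia that include the stem cells of the testis. The comparison asks which transcripts differ when ID4 is held high in these cells. Expression is given as the authors' FPKM, 1 value per group over its 3 replicates, so every value below lacks a replicate SD and the spread between animals enters only through the authors' test. Summed FPKM was 789669 in controls and 801581 with overexpression, and the median of tested genes was 10.9 and 11.2 FPKM. The overexpression sum includes 49560.8 FPKM of Snora30, an entry that the authors did not test and that is at 0 in controls. That value is larger than the gap between the sums. Depth per sample is unknown.

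Id4 itself was higher in the overexpression group. It lies on chromosome 13, positions 48261427 to 48264036 of GRCm38, on the plus strand, and the table does not separate transgenic from endogenous transcript. Its level was 6.37 FPKM in controls and 13.4 FPKM with overexpression, 2.11-fold higher, and the authors' deposited table lists q = 0.000835, the smallest value in it.

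Across the transcriptome, the genes that rose most included macrophage and chemokine genes, and those that fell most included markers of differentiating spermatogonia. Of 10990 tested genes, 1869 (17.0%) were called: 1054 were higher and 815 lower with overexpression. The median fold was 1.92 among higher calls and 1.73, control over overexpression, among lower calls, and 38.8% of calls changed at least 2-fold. The largest rise was in Plaur, the urokinase receptor, from 1.59 to 19.5 FPKM (12.3-fold; chromosome 7, 24462500 to 24475873). C1qc, a complement component made by macrophages, rose 8.50-fold to 7.56 FPKM. Ccl2, a chemokine that recruits monocytes, rose from 10.5 to 78.8 FPKM, and the bHLH repressor Bhlhe40 rose from 0.901 to 6.63 FPKM. Clec12b, Adam32, H2-Ab1, Dnajc5b and Hmgb4 were also among the 10 largest rises. Ccl2, Dnajc5b and Hmgb4 overlap another protein-coding gene, and since the use of strand is not stated, reads of the partners cannot be separated.

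The largest decrease was in Nppc, which encodes C-type natriuretic peptide, from 3.45 to 0.510 FPKM (log2 change -2.76; chromosome 1, 86666293 to 86670573). Alox12b, a lipoxygenase, fell from 5.16 to 0.945 FPKM, and Tph1, a tryptophan hydroxylase of serotonin synthesis, from 2.68 to 0.513 FPKM. Nrtn, which encodes the GDNF-family ligand neurturin, fell from 3.76 to 0.759 FPKM. Prss50 and Ly6k, both on the list of differentiating spermatogonia, fell to 1.48 and 5.43 FPKM from 7.44 and 24.1 FPKM. Aif1l, Guca1a, Hrh1 and Cpne2 complete the 10 largest decreases. In the authors' deposited table q was 0.000835 for Plaur, C1qc, Ccl2, Bhlhe40, Alox12b, Prss50 and Ly6k, 0.0221 for Nppc, 0.0033 for Tph1 and 0.0271 for Nrtn.

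Many genes of the stem-cell state rose. Of 22 tested members, 14 were higher and 0 lower, with a median log2 fold change of 0.73; 5 lay below 0, none of them called. Lhx1, a GDNF-induced homeobox factor, rose from 2.79 to 11.9 FPKM, and the chemokine receptor Cxcr4 from 1.75 to 5.26 FPKM. Bcl6b, a repressor needed for stem-cell maintenance, rose from 14.0 to 36.2 FPKM, and Gfra1, the GDNF co-receptor, from 15.8 to 37.3 FPKM. Id4, the gene overexpressed by design, is itself a member; without it 13 of 21 were higher (Fisher's exact test, adjusted p = 6.58e-08). The higher calls exceeded those among other tested genes (63.6% against 9.49%; Fisher's exact test, adjusted p = 9.88e-09), and no random list of matched expression had a higher median. Adjusted over the list alone, 14 were higher and 1 lower. In the same comparison 14 of 15 macrophage markers and 10 of 15 Sertoli cell markers were higher.

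Genes that respond to GDNF, the niche factor that sustains spermatogonial stem cells through the RET receptor, rose as well. Of 21 tested members, 15 were higher and 0 lower, with a median of 1.02, above all matched random lists (Fisher's exact test, adjusted p = 3.82e-10; 15 and 0 adjusted over the list alone). Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, rose from 3.23 to 14.6 FPKM, and the ETS factor Etv4 from 2.52 to 8.35 FPKM. The list shares 12 tested members with the stem-cell-state list, Lhx1, Cxcr4 and Id4 among them, so the counts are not independent. Without Id4, 14 of 20 were higher, with a median of 0.90 (Fisher's exact test, adjusted p = 2.85e-09). Alongside it, macrophage and Sertoli cell markers had medians of 2.07 and 1.52.

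Progenitor and differentiating spermatogonia markers moved the other way. Of 9 tested progenitor genes, 0 were higher and 6 were lower, with a median of -0.53, at percentile 0.02 of matched random lists (Fisher's exact test, adjusted p = 9.44e-05; 6 lower adjusted over the list alone). Upp1, a uridine phosphorylase, fell from 60.7 to 20.1 FPKM. Neurog3, a bHLH factor of progenitors that overlaps Fam241b, fell from 8.33 to 4.03 FPKM, and Sox3 fell from 6.97 to 4.21 FPKM. At an authors' q threshold of 0.01 the progenitor list no longer passed (adjusted p = 0.164, Fisher's exact test). Here too, macrophage and Sertoli cell markers had medians of 2.07 and 1.52. Dilution by RNA of other cells was not tested for the progenitor list.

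Of 15 tested genes of differentiating spermatogonia, 11 were lower and 1 higher, with a median of -1.10, below all matched random lists (Fisher's exact test for lower calls, adjusted p = 6.07e-09). Adjusted over the list alone the counts were again 11 and 1. Lmo1, a LIM-domain cofactor, fell from 11.01 to 2.77 FPKM, and Crabp1, which binds retinoic acid in the cytoplasm, from 544.4 to 189 FPKM. Kit, the receptor that marks differentiating spermatogonia, and Stra8, a retinoic acid target needed for meiosis, had log2 changes of -1.14 and -1.19, both called; they were chosen after their values were seen. The higher member was the cyclin Ccnd2, which rose from 89.5 to 206 FPKM and is also on the GDNF list. Ly6k lies on chromosome 15, where 56.2% of tested genes were lower, and 10 of the 14 members outside that chromosome were lower. Macrophage and Sertoli cell markers were higher in the same comparison, with medians of 2.07 and 1.52.

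General markers of undifferentiated spermatogonia showed no shared direction. Of 17 tested, 1 was higher and 3 were lower, with a median of -0.05 at percentile 28.9 of random lists (1 and 4 adjusted over the list alone; Fisher's exact test, adjusted p = 1 for higher and 0.289 for lower calls). Dusp6, a phosphatase that limits ERK signalling, rose from 52.9 to 129 FPKM. Uchl1, a ubiquitin hydrolase abundant in spermatogonia, fell from 695.8 to 464 FPKM, Lin28a from 55.5 to 40.8 FPKM and Utf1 from 2.92 to 1.21 FPKM. Zbtb16, which encodes PLZF, had a log2 change of -0.05 and was not called; it was chosen after its value was seen. Of 18 pan-germ-cell genes, 0 were higher and 4 were lower, with a median of -0.16 at percentile 3.16 and the same counts adjusted over the list alone (Fisher's exact test for lower calls, adjusted p = 0.111). The 4 were Mov10l1 (147 to 87.9 FPKM; chromosome 15), Piwil2 (149 to 99.3 FPKM), Piwil4 (17.1 to 11.5 FPKM) and Tdrd9, which overlaps Rd3l (37.8 to 25.9 FPKM). Beside both lists, macrophage and Sertoli cell markers had medians of 2.07 and 1.52.

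**Figure D1:**
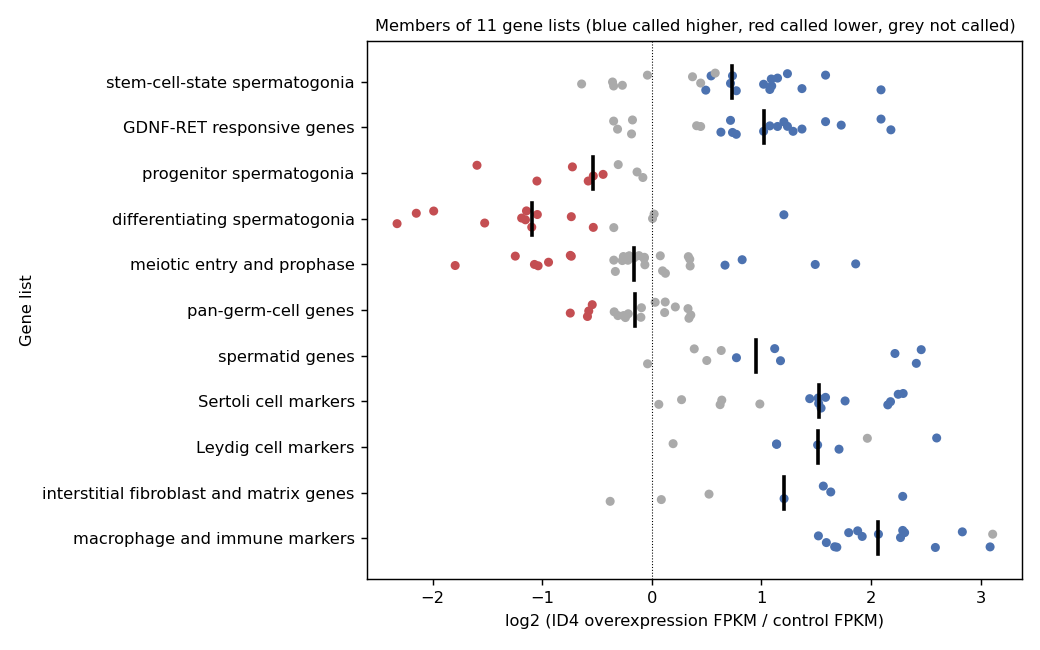
Log2 ratio of overexpression to control FPKM (horizontal axis) for the tested members of 11 gene lists (vertical axis); each point is a gene, coloured by whether it was called higher, called lower or not called, and the black bars are list medians. The stem-cell-state and GDNF lists have medians of 0.73 and 1.02, the progenitor and differentiating lists -0.53 and -1.10, and the macrophage markers 2.07.

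Meiotic genes were split. Of 29 tested genes of meiotic entry and prophase, 7 were lower and 4 were higher, with the same counts adjusted over the list alone, and the median was -0.16, at percentile 1.76 of random lists. Mei1, needed for meiotic double-strand breaks, fell from 13.0 to 3.73 FPKM, and Syce3, a synaptonemal complex protein, from 136 to 57.3 FPKM. Ldhc and Pgk2, metabolic enzymes specific to spermatocytes and later cells, rose from 4.89 to 13.7 and from 0.538 to 1.96 FPKM. Lower calls passed the test (Fisher's exact test, adjusted p = 0.0171). However, 4 of the 7, Mei1, Syce3, Smc1b and Dmc1, lie on chromosome 15, and without that chromosome the adjusted p was 0.341. Smc1b and Dmc1 were named after their values were seen. Macrophage, Sertoli cell and spermatid genes had medians of 2.07, 1.52 and 0.95 in the same comparison.

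Spermatid genes rose. The authors tested 10 of the 20 genes on the list. Of these 10, 6 were higher and 0 lower, with a median of 0.95, above all matched random lists, and the same counts adjusted over the list alone (Fisher's exact test, adjusted p = 0.000719). The protamine genes Prm1 and Prm2, whose products replace histones in sperm chromatin, rose from 35.9 to 192 FPKM and from 4.52 to 24.8 FPKM. The transition protein gene Tnp2 rose from 5.20 to 24.2 FPKM and Akap4, of the sperm tail, from 1.08 to 2.44 FPKM. Prm1, Prm2 and Tnp2 lie close together on chromosome 16 (10787935 to 10796823). They may therefore not be independent, although the test and the random lists treat them so. Macrophage and Sertoli cell markers were higher in the same comparison, with medians of 2.07 and 1.52.

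Genes of retinoic acid handling, the signal that starts spermatogonial differentiation, moved in both directions. Of 13 tested, 5 were lower and 4 higher, with the same counts adjusted over the list alone and a median of -0.24 at percentile 2.30 of random lists (Fisher's exact test, adjusted p = 0.00785 for lower and 0.0876 for higher calls). At an authors' q of 0.01 the higher calls passed as well (adjusted p = 0.0254, Fisher's exact test). Crabp1 fell from 544.4 to 189 FPKM. The retinaldehyde dehydrogenase genes Aldh1a1 and Aldh1a3 rose from 2.90 to 8.88 and from 1.34 to 3.54 FPKM, while Aldh1a2, the most abundant of the 3 and named after its values were seen, fell from 17.2 to 7.31 FPKM. Beside this list, the medians of macrophage and Sertoli cell markers were 2.07 and 1.52.

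Among ID and bHLH factors, the binding partners and relatives of ID4, 6 of 21 were higher and 4 were lower, with a median of 0.01 at percentile 45.5 of random lists, which became -0.01 once the median of all expressed genes was subtracted. Adjusted over the list alone, 6 were higher and 6 lower. Bhlhe40 and Id4 rose, and Mycl1, a MYC family member, and Ascl2 fell from 3.90 to 1.16 and from 11.9 to 5.41 FPKM. Id2 and Id3, chosen after their values were seen, also rose, by 0.65 and 0.78 on the log2 scale, and Id1 had a value of -0.63 and was not called. Higher calls passed only with Id4 counted (Fisher's exact test, adjusted p = 0.0422); without it, 5 of 20 were higher, the median was -0.04 and the adjusted p was 0.108. They did not pass at an authors' q of 0.01 (0.124) or without chromosome 15 (0.0507), where the list has no tested member and its counts stayed the same. In the same comparison the macrophage and Sertoli cell marker medians were 2.07 and 1.52.

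Some p53 target genes rose. Of 16 tested genes of apoptosis and the p53 response, 5 were higher and 0 lower (5 and 1 adjusted over the list alone), with a median of 0.17 at percentile 95.8. Pmaip1, which encodes the pro-apoptotic protein NOXA, rose from 42.2 to 186 FPKM, and the CDK inhibitor gene Cdkn1a from 4.47 to 18.2 FPKM. Ccng1, a p53 target, rose from 13.3 to 30.7 FPKM. The list passed (Fisher's exact test, adjusted p = 0.0477), but not at an authors' q of 0.01 (0.19), without chromosome 15 (0.0561) or without Id4 (0.0509). It has no tested member on that chromosome and does not hold Id4, so 5 of 16 remained higher in both of these settings. Among 13 CDK inhibitor and RB family genes, 4 were higher and 1 lower (5 and 1 adjusted over the list alone), with a median of 0.20 at percentile 93.4 (Fisher's exact test for higher calls, adjusted p = 0.0876). The higher members were the inhibitor genes Cdkn1a and Cdkn2b (1.28 to 3.44 FPKM) and the cycle drivers Ccnd2 and Cdk4 (224 to 323 FPKM), the last named after its values were seen. Cdk6 fell by 1.20 on the log2 scale. Macrophage and Sertoli cell markers were higher beside both lists, with medians of 2.07 and 1.52.

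Many immediate-early and dissociation stress genes were higher. Of 18 tested, 9 were higher and 1 lower (11 and 1 adjusted over the list alone), with a median of 0.57, above all matched random lists (Fisher's exact test, adjusted p = 0.000104). Cyr61 rose from 1.40 to 6.24 FPKM, the stress factor Atf3 from 1.48 to 5.12 FPKM, and the zinc-finger genes Klf6 and Egr1 from 8.63 to 19.05 and from 18.9 to 33.6 FPKM. The lower member was Klf4, at a log2 change of -0.64, named after its value was seen. The immediate-early gene Fos, also named after its values were seen, went from 74.9 to 65.9 FPKM and was not called. Macrophage and Sertoli cell markers were higher beside this list, with medians of 2.07 and 1.52.

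Markers of other testis cell types were higher in the overexpression group. Among macrophage and immune markers, 14 of 15 tested were higher and 0 lower, with a median of 2.07 (Fisher's exact test, adjusted p = 3.54e-12). C1qb rose from 5.62 to 27.8 FPKM, Aif1 from 2.93 to 17.6 FPKM and the class II gene H2-Ab1 from 0.464 to 3.31 FPKM. Of 15 Sertoli cell markers, 10 were higher and 0 lower (12 and 0 adjusted over the list alone), with a median of 1.52 (Fisher's exact test, adjusted p = 1.22e-06). Inha, the inhibin alpha subunit gene, rose from 5.81 to 28.5 FPKM, Kitl, the ligand of KIT, from 0.605 to 2.88 FPKM, and Cst12 from 14.5 to 65.8 FPKM. Of 7 Leydig cell markers, 5 were higher and 0 lower, with a median of 1.51 (Fisher's exact test, adjusted p = 0.000797). Cyp11a1, which starts steroid synthesis, rose from 6.31 to 20.6 FPKM, and Hsd3b1 from 9.78 to 27.9 FPKM. Of 7 interstitial fibroblast and matrix genes, 4 were higher and 0 lower, with a median of 1.21 (Fisher's exact test, adjusted p = 0.00969), among them Sparc, from 11.5 to 34.1 FPKM, and Pdgfra, from 2.33 to 5.39 FPKM. The counts for macrophage, Leydig and fibroblast genes were the same adjusted over the list alone. These counts cover tested genes only. The authors did not test 2 of 17 macrophage, 9 of 24 Sertoli, 5 of 12 Leydig and 11 of 18 fibroblast genes on the lists. The bootstrap interval of the fibroblast median was 0.09 to 1.63. Controls had an FPKM of at least 1 for 12 of the 15 macrophage, 13 of the 15 Sertoli, 6 of the 7 Leydig and 6 of the 7 fibroblast genes tested.

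Other lineages gave little signal. Of 2 tested endothelial markers, 0 were higher and 1 was lower: Egfl7, which overlaps Agpat2 and Gm20532, fell from 20.98 to 13.7 FPKM. The authors tested 0 of 11 peritubular myoid and smooth muscle markers, whose highest levels were 1.45 FPKM in controls and 1.39 FPKM with overexpression. They tested 0 of 7 erythroid markers, whose highest levels were 0.977 and 0.536 FPKM.

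Genes of chromosome 15 were lower along its whole measured length. Of 413 tested genes there, 232 (56.2%) were lower, against 583 of 10572 (5.51%) elsewhere, an odds ratio of 22.0 (Fisher's exact test, adjusted p = 7.97e-159). They made up 28.5% of all lower calls. Higher calls were fewer there, 16 of 413 or 3.87%, against 9.82% elsewhere (Fisher's exact test, adjusted p = 0.000247). Among genes with FPKM of at least 5, the median log2 fold change was -0.65 on chromosome 15 (310 genes) and 0.02 on the other autosomes (7438 genes), whose single medians ran from -0.02 to 0.08. Values lay below 0 for 93.5% of the chromosome 15 genes and for 47.7% of the others. The respiratory chain genes Cyc1 (226 to 88.4 FPKM; 76343523 to 76345934) and Cox6c, which overlaps Vps13b (1852 to 1048 FPKM; 35931976 to 35938246), lie there.

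**Figure D2:**
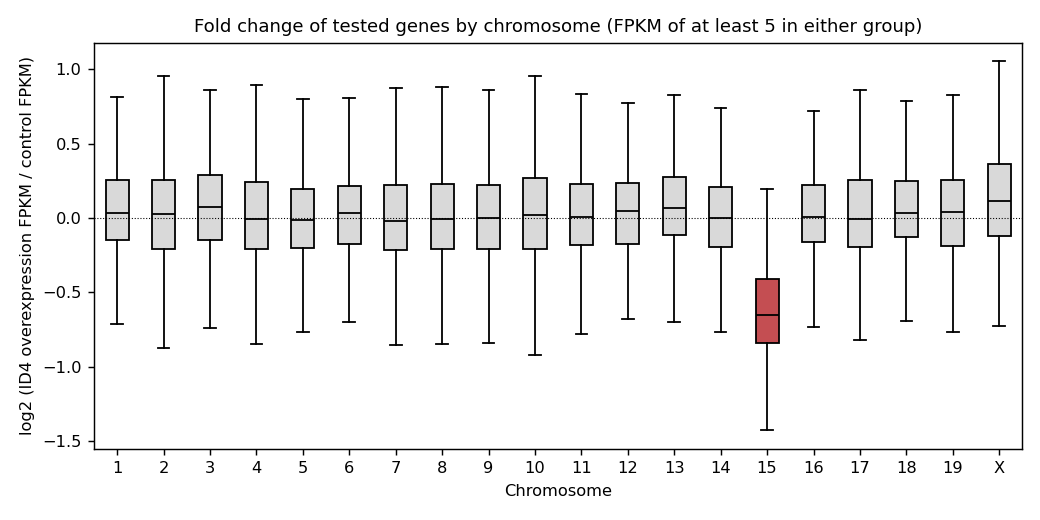
Log2 ratio of overexpression to control FPKM (vertical axis) per chromosome (horizontal axis) for tested genes with FPKM of at least 5 in either group, drawn as boxes of the quartiles with the median as a line. Chromosome 15 has a median of -0.65, and the other autosomes lie between -0.02 and 0.08.

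The decrease was not limited to a segment. All 8 intervals of 10 Mb with enough genes had medians between -0.76 and -0.38, and the lowest of 206 such intervals on the other autosomes was -0.17. Outside chromosome 15, 1038 genes were higher and 583 lower, so that 64.0% of calls were higher, against 56.4% over the whole table. On the X chromosome 63 of 445 tested genes (14.2%) were higher, against 9.40% elsewhere (Fisher's exact test, adjusted p = 0.0142), and the median was 0.11. Chromosome 5 had fewer higher calls (6.66%; adjusted p = 0.0285, Fisher's exact test), and 7 chromosomes had fewer lower calls than the rest of the genome (Fisher's exact test, adjusted p of 0.0347 or less). With chromosome 15 genes left out, 0 of 40 such Fisher's exact tests passed, and the smallest adjusted p was 0.0579. The shares of higher calls moved little in that setting: 14.2% on X against 9.63% elsewhere, and 6.66% on chromosome 5 against 10.04% (Fisher's exact test, unadjusted p = 0.00254 and 0.00289).

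**Figure D3:**
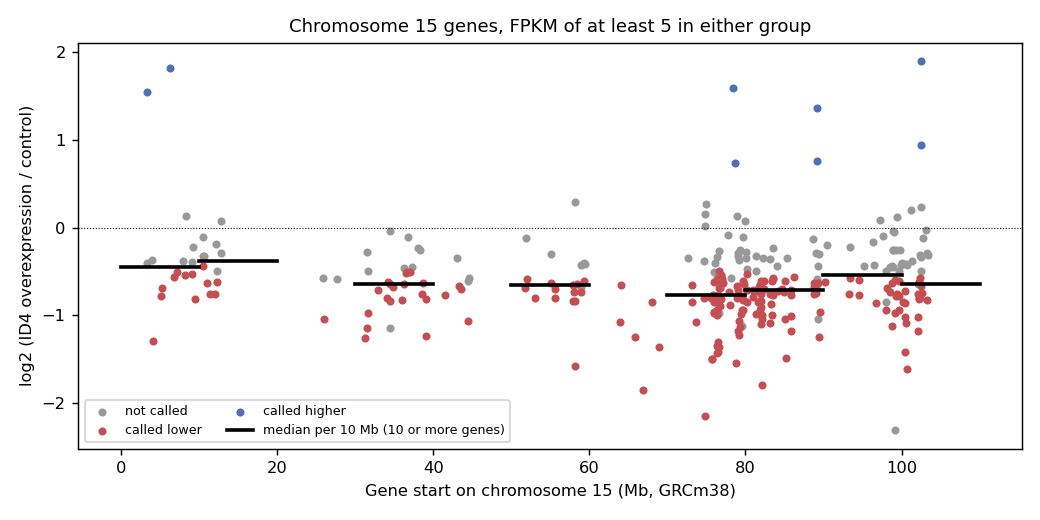
Log2 ratio of overexpression to control (vertical axis) against gene start on chromosome 15 in Mb of GRCm38 (horizontal axis) for 310 tested genes with FPKM of at least 5 in either group; points are genes coloured by call, and black bars are medians of 10 Mb intervals with at least 10 genes. Interval medians lie between -0.76 and -0.38.

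Apart from glycolysis, proliferation and housekeeping lists held few called genes, while several of their medians lay at the edge of the matched random lists. Of 30 S-phase genes, 2 were higher and 0 lower (median 0.16, percentile 99.7), and of 30 G2 and M phase genes, 3 were higher and 0 lower (median 0.20, percentile 99.9). Values lay above 0 for 24 of the S-phase and 27 of the G2 and M phase genes. Rrm2, a ribonucleotide reductase subunit gene, rose from 99.2 to 145 FPKM and the cyclin gene Ccnb2 from 99.6 to 147 FPKM. Of 20 glycolysis genes, 4 were higher and 1 lower (5 and 1 adjusted over the list alone; median 0.07, percentile 78.2), with Ldhb rising from 18.3 to 49.2 FPKM. Of 39 oxidative phosphorylation genes, 1 was higher and 3 were lower (median -0.03, percentile 49.0). The 3 were Cyc1, Cox6c and Ndufb9, all on chromosome 15, and the higher member was Uqcrc1. Of 83 ribosomal protein genes, 0 were higher and 3 lower, and 69 lay below 0 (median -0.15, percentile 0.01); higher calls were fewer than elsewhere (Fisher's exact test, adjusted p = 0.0024). Of those 3, Rpl8 and Rpl37 lie on chromosome 15 and Rpl22l1 does not, and processed pseudogenes make values of ribosomal genes uncertain. Of 18 tested replication-dependent histone genes, 0 were called and 16 lay above 0 (median 0.40, percentile 99.8), and their transcripts mostly lack the poly(A) tail that the priming needs. Of 19 FOXO and mTORC1 regulators, 0 were higher and 2 were lower, Sesn3 and Akt1 (13.5 to 7.67 FPKM; median -0.04, percentile 27.8). Counts adjusted over the list alone were the same where not given. Lists in this paragraph other than the ribosomal genes had adjusted p of at least 0.282 by Fisher's exact test in either direction, and the macrophage and Sertoli cell markers beside them had medians of 2.07 and 1.52.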

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

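These values lie outside the genes that the authors tested, and no test was applied to them. Each of the following short RNAs was listed at 0 FPKM in controls and above 100 FPKM with overexpression, in entries that the authors did not test. Snora30, a small nucleolar RNA, was listed at 49560.8 FPKM with overexpression. Snora44 was listed at 176.8 FPKM and the small Cajal body RNA gene Scarna3a at 144.1 FPKM. No fold is given against a group at 0, and no explanation was tested.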

How the results depend on the processing

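The settings without chromosome 15 and without Id4 were chosen after seeing the data, and the others were planned. The 1054 higher and 815 lower calls became 664 and 450 at an authors' q of 0.01, and 491 and 235 with an absolute log2 fold change of at least 1; other settings left them within 1.5 times. At a q of 0.01, adjusted p from Fisher's exact test rose to 0.164 for progenitor genes (lower), 0.124 for ID and bHLH factors (higher), 0.19 for p53 targets (higher), 0.0564 for chromosome 8 (lower) and 0.0744 for chromosome 13 (lower). Without chromosome 15 it rose to 0.341 for meiotic genes (lower), 0.0507 for ID and bHLH factors and 0.0561 for p53 targets. In that setting it was 0.245 for chromosomes 3 and 13 (lower), 0.769 for 8, 10, 11 and 17 (lower), 0.538 for 19 (lower), and 0.0579 for 5 and X (higher). Without Id4 it was 0.108 for ID and bHLH factors and 0.0509 for p53 targets. The ID and bHLH and the p53 lists have no tested member on chromosome 15, and the shares of higher calls on 5 and X moved little, so their losses without chromosome 15 came with small shifts in background and adjustment. Chromosomes 3, 8, 10, 11, 13, 17 and 19 kept their own counts of lower calls, while the share elsewhere fell by construction (for chromosome 3, from 7.62% to 5.62%), and the meiotic list lost 4 of its 7 lower calls. For the losses at a q of 0.01 the cause was not tested. The FPKM minimum of 1 removed no tested gene, so it shows nothing and is left out of these totals. Over the other settings, 46 Fisher results kept their side of the threshold, 19 lost it and 4 gained it: at a q of 0.01, retinoic acid genes (higher, 0.0254), chromosomes 1 (lower, 0.0163) and 5 (lower, 0.0248), and chromosome 12 (higher, 0.0248). The 46 include lists without Id4 or without a tested member on chromosome 15. For these lists the matching setting removed no member, so keeping their side shows little. Of the list medians, 86 stayed within their bootstrap interval, not counting lists from which a setting removed no gene; macrophage markers fell to 1.59 with a pseudocount of 1. No called result changed direction, which shows little. A pseudocount cannot change the sign of a gene's log2 ratio, and a q threshold does not alter that ratio. The subtracted median log2 fold change was only 0.0149, so the 86 medians also include settings that could move a median little. The median of ID and bHLH factors went from 0.01 to -0.01 when the median log2 fold change was subtracted, and to -0.04 without Id4. No paired analysis was possible because only values per group were used; leaving out replicates, a pseudocount per sample and another tool were not run for the same reason. Depth is unknown, so it sets no stated limit on genes of low FPKM.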

Other observations

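Several tests in this part were chosen only after the result was seen. They are those of chromosome copies, chromosome segments, the share of germ cells and dilution. The tests of genes taken as germ-line-restricted and of the chromosome 15 part of the differentiating list are also among them. The gene families described next were picked after members were seen among the rises, so no test is given for them. Of 13 tested chemokine ligand genes, 7 were higher and 0 lower. Macrophage and Sertoli cell markers, with medians of 2.07 and 1.52, were higher in the same comparison. The ligand genes were Ccl2, Ccl3, Ccl4, Ccl7, Ccl12, Ccl24 and Cxcl2. Of 17 glutathione S-transferase genes, 7 were higher, including Gstm1, Gsta4 and Gstm6, the last of which is also on the Sertoli list; several are near-identical paralogs, so their single values are uncertain. Of 4 Hox genes, Hoxb5 and Hoxb7 were higher.

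Among DNA and histone methylation genes, 3 of 22 tested were higher and 4 lower (4 and 4 adjusted over the list alone), with a median of 0.02 at percentile 54.5 of random lists. The germ-line cofactor gene Dnmt3l, which overlaps Aire, fell from 2.19 to 0.538 FPKM, and the de novo methyltransferase gene Dnmt3b from 25.3 to 12.2 FPKM. Tet3, which oxidises methylcytosine, fell from 5.26 to 3.04 FPKM, and the Polycomb gene Scmh1 rose from 11.2 to 20.6 FPKM. Neither direction passed (Fisher's exact test, adjusted p = 0.702 for higher and 0.189 for lower calls).

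For the decrease across chromosome 15, the values argue against a trend on GC content or transcript length as its whole cause, since the median was -0.69 after that trend was removed (95% interval -0.74 to -0.66) and -0.65 before. A change in part of the chromosome is also opposed, as the highest interval median was -0.38. A candidate explanation is a different number of copies of chromosome 15 between the groups: the median relative to other autosomes was -0.67 (95% interval -0.71 to -0.63), below the -0.58 of 2 copies against 3, and the spread of its genes was 0.997 times that elsewhere. If RNA followed gene copies in proportion, the control to overexpression ratio of 1.59 would need 3.19 copies in all 3 controls (95% interval 3.10 to 3.28). It would need 3.78 copies if 2 controls carried a gain, 5.56 copies if 1 did, or 1.25 copies in every overexpression sample if controls had 2. No whole number of copies lies in the 95% interval of any of these cases. The proportion of RNA to copies was assumed, and the intervals cover genes, not variation between animals. A copy difference was proposed after the median was seen, so these values cannot serve as independent support for it. Interval medians from -0.76 to -0.38 along the chromosome are not modelled by it. Which group or samples would carry a copy difference, and whether ID4 itself lowers these genes, was not tested.

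Markers of other testis cells may be higher because the sorted cells held more RNA of those cells. A second set of macrophage genes, written down before its values were seen, had a median of 1.49, with 19 of 19 tested genes (of 29) above 0 and 17 called higher, which is consistent with more macrophage RNA in the overexpression group. The most abundant listed macrophage marker, Lyz2, went from 24.1 to 77.8 FPKM. Selection on the ID4 reporter is meant to leave out macrophages, but the purity of the sorted cells is not known here. A lower share of germ cells with other types in unchanged proportion cannot be told apart from more macrophage RNA. Macrophage markers rose more than Sertoli, Leydig and fibroblast markers (medians 2.07 and 1.52, 15 and 29 genes, permutation p = 0.0344). Some markers, such as Ctsl at 111 FPKM in controls and not called, may have a baseline in germ cells, so that test is not decisive. The members called higher gave a permutation p of 0.164. Calling selects on the fold being compared, which can shrink the gap, so that second test cannot decide either. Expression of these genes by the germ cells themselves was not tested.

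Position on chromosome 15 does not account for the rise of stem-cell-state genes with the fall of differentiating genes. Of tested genes, 0 of 22 stem-cell-state and 1 of 15 differentiating genes lie there, and 10 of 14 differentiating genes elsewhere were lower. Leaving out the chromosome could therefore change little. It cannot address an effect of the chromosome 15 difference on genes elsewhere. For the fall, the values oppose dilution by RNA of cells that lack both differentiating and pan-germ-cell genes. The differentiating genes had a median of -1.10 against -0.16 for pan-germ-cell genes (permutation p = 0.00134, over genes and not samples). Added germ cells of later stages that express pan-germ-cell genes need not lower that list, and spermatid genes had a median of 0.95. Dilution by RNA of such cells was not tested. The rise of stem-cell-state genes cannot be told apart from an addition of RNA of other cells. Of 3 tested members taken here as germ-line-restricted, 2 (Nanos2 and Tcl1) were higher and Rhox10, at -0.27, was not called. Their restriction to germ cells was assumed and not tested, and immune markers rose in the same comparison. A shift of the sorted cells toward the stem-cell state with ID4 overexpression may contribute, and remains a hypothesis found and tested on the same data.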
